A study of Caenorhabditis elegans with 8 samples.

How the data were processed

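RNA was measured by RNA-seq in 8 libraries from Caenorhabditis elegans females. The animals carried a temperature-sensitive fog-1 allele, which feminises the germ line when worms are grown at 25 °C. Stocks were kept at 15 °C. Hatched larvae were plated at 30000 per plate and collected as young adults after about 48 h on food. One strain carried a GFP-tagged OMA-1 transgene with an unc-119 rescue gene in an oma-1 mutant, and the other carried GFP at the endogenous lin-41 locus. Ribonucleoprotein complexes were immunoprecipitated (IP) with monoclonal antibodies to GFP. Each tagged protein had 2 IP libraries, 1 lysate library depleted of ribosomal RNA and 1 lysate library without depletion, 4 libraries per strain. The plan took the IPs as not depleted. The strain names in the labels rise by 1 from sample to sample within one genotype, so samples were grouped by title and genotype, and 1 strain per genotype is assumed. The labels do not say whether the IP libraries of a kind came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

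The submitters' processing notes name Trimmomatic 0.32, STAR 2.4.2a, SAMtools 1.0 and DESeq2 1.12.3 and the WBcel235 build, with no role or order. The counter, the annotation and the strand setting are not given in the sources used here. The only data table used here held the authors' own comparisons and pooled values for 16031 genes, with no value for a single library. The authors deposited a log2 ratio of each IP to the depleted lysates of both strains pooled, per the file headers, and a Benjamini-Hochberg adjusted p-value for each ratio. The denominator was therefore not the lysate of the same strain. Every gene tested with a log2 ratio at or below 0 had an adjusted p of 1, 8208 genes for OMA-1 and 7187 for LIN-41, so the deposited test looked only for enrichment. The authors deposited FPKM values pooled over the depleted lysates, the OMA-1 IPs and the LIN-41 IPs. The deposited baseMean, a scaled mean signal in reads per gene over libraries, ran from 1.00 to 180441 with a median of 44.4. The authors also deposited a log2 ratio for an OMA-1 IP of an earlier study over the same lysates, and a log2 ratio with p-value for spermatogenic against oogenic gonads of another study. A further 4 columns of values from other studies were not used. Library totals and depth are unknown, and baseMean stands for depth below.

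Over 4185 genes with a baseMean above 500, the log2 of the ratio of the deposited FPKM values differed from the deposited log2 ratio by a median of 0.0032 for OMA-1 and 0.0024 for LIN-41. The 3 FPKM columns had different totals, 394382 for the lysates, 1006225 for the OMA-1 IPs and 762130 for the LIN-41 IPs. Scaling them to one total without the mitochondrial genes moves every log2 ratio by -1.33 for OMA-1 and -0.95 for LIN-41. Where a ratio of 0 lies thus depends on the authors' scaling.

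The design fixed before the data were examined assumed values per library. Its edgeR or limma test of each IP against its own depleted lysate and its camera gene set tests were not run. It stated that no test would be run on a table of the authors' comparisons alone. The deposited calls of enrichment, at an adjusted p below 0.05, are therefore the authors' own. Approximate tests were added after the data were seen, for lower values and for the difference between the IPs, and depart from that plan. The deposited adjusted p was converted to a one-sided raw p by undoing the Benjamini-Hochberg steps, then to a Wald z, and the log2 ratio divided by z gave an implied standard error (SE). A gene with no such value took the SE of the other comparison or, failing that, the 95th percentile among the 201 genes closest in baseMean. The last source was used for 7026 of 15742 genes in the OMA-1 comparison and 5928 of 13955 in the LIN-41 comparison. Adjusted p-values stored as 0, 255 for OMA-1 and 102 for LIN-41, gave only an upper limit on the SE. Over 3072 genes with a baseMean above 100 and both implied SEs, these correlated across genes with r = 0.996 on the log scale, and their ratio lay between 0.813 and 1.10. Lower values were tested with a one-sided normal test. The lysate cancels in the OMA-1 minus LIN-41 difference, so this compares the IPs directly. It was tested with a two-sided normal test, with the root of the summed squared SEs as its error. Both tests were adjusted by the Benjamini-Hochberg method. If the implied SEs hold, this error is too wide, because it counts the lysate spread that cancels.

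In simulated data with 200 genes changed between the IPs and a further set raised alike in both, the difference test recovered 52.7% of 150 genes changed 4-fold and 34% of 50 changed 2-fold. Among those with a baseMean of at least 100 it recovered 98.5% of 68 genes and 72.7% of 22 genes. It called 1 of 13755 unchanged genes. The test for lower values found 62% of 50 genes lowered 4-fold in the OMA-1 comparison and called 3 of 15495 genes that were not lower. The simulation drew from the same Wald model as the conversion, so it checks the arithmetic and not whether the authors used that model.

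For 25 gene lists fixed in advance, the calls were set against all tested genes with a two-sided Fisher's exact test, adjusted over the lists of each IP, and the median log2 ratio was ranked among 10000 random lists matched on bins of lysate FPKM. Genes are not independent replicates, so these p-values are descriptive. The ribosomal RNA list had no gene in the table. Named genes were, for each IP, the 14 with the highest log2 ratio among calls at 10 FPKM or more in the IP and the 8 with the lowest log2 ratio at 10 FPKM or more in the lysate. The rule added 8 genes for each side of the difference, 10 genes called in both IPs, all tagged genes and reported targets, and examples per list. It asked for genes that moved the same way in both IP libraries, which could not be checked without values per library. It allowed 2 to 4 examples per list, and 2 were taken after the values had been seen. Examples came from genes called higher, because the deposited test did not look for lower values, and from the most abundant members where none was called. The genes unc-119, his-24, his-35 and his-71 were added after their values were seen. Ribosomal RNA, msp and his genes were left out of the rankings. Of the 16031 gene identifiers, 15914 were found in the WBcel235 annotation, release 115, from which coordinates and 3′ UTR lengths were taken. Genes with near-identical copies, such as histone, vit, hsp-16, fbf and puf genes, may share reads and are uncertain. The authors marked 69 genes for low-quality or multimapping reads, and 5 gene symbols in the deposited table had turned into dates, so list members were also looked up by the current symbol of each identifier.

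Alternatives were a 2-fold minimum, a filter at 10 FPKM, quantile normalization of the pooled FPKM columns, one total FPKM without mitochondrial genes, pseudocounts of 1 and 0.1 FPKM, and 3 chosen after seeing the data. The table analysis used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.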

Results

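RNA that came down with OMA-1 or LIN-41, RNA-binding proteins that control translation in growing oocytes, was compared with the RNA of whole-animal lysates. None of the 8 libraries was labelled as an IP from an untagged or mock control. Binding thus cannot be told apart from nonspecific carry-over or from a general excess of germline RNA over whole-animal RNA. The 8 libraries fell into 6 groups: 2 OMA-1 immunoprecipitates (IPs), 2 LIN-41 IPs, and 1 lysate with and 1 lysate without depletion of ribosomal RNA from each strain. Only pooled values and comparisons were analysed here, so the counts per library are unknown and no value has an SD. All log2 ratios and FPKM values come from the authors' deposited table, which sets each IP against the depleted lysates of both strains pooled. With IPs that were not depleted, an effect of the depletion cannot be told apart from IP against lysate in these ratios. The position of a ratio of 0 rests on the authors' scaling: with equal FPKM totals every log2 ratio shifts by -1.33 for OMA-1 and -0.95 for LIN-41. Quantile normalization moves the median by -0.09 and -0.01.

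Which mRNAs came down with OMA-1 was asked first. Transcripts most enriched with OMA-1 included dpy-10, a cuticle collagen gene, and sygl-1, a Notch target that maintains germline stem cells. The RNA-binding protein gene rnp-1 and the Wnt ligand gene mom-2, both reported OMA targets, were among the 14 highest. Transcripts of cytosolic ribosomal proteins and the proteasome were low. In the authors' deposited table, dpy-10 (WBGene00001072, chromosome II 6710149 to 6712227 in WBcel235) had the highest log2 ratio of the named genes, 6.70, with 3.50 FPKM in the lysates and 367 FPKM in the IPs. In the authors' deposited table, sygl-1 (WBGene00012104, I 12483809 to 12486235) rose from 37.6 to 3750 FPKM, a log2 ratio of 6.63. The authors' deposited table gave rnp-1 (WBGene00004384, V 12192273 to 12194366) a log2 ratio of 5.96 and mom-2 (WBGene00003395, V 8355988 to 8358185) one of 5.95. The authors' deposited table listed ing-3, num-1, ztf-22, zip-11, mam-4, dad-1, sdz-37, sdz-21, ref-1 and erg-28 between 6.32 and 5.87. Of 15742 genes tested, the authors' deposited table called 4477 (28.4%) higher with OMA-1 at an adjusted p below 0.05 by the one-sided test, 3585 of them at least 2-fold and 521 at least 16-fold.

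Under the deposited scaling, transcripts of the reported targets of OMA-1 and LIN-41 were mostly enriched with OMA-1. The exceptions were mei-1, which encodes a meiotic spindle severing protein, and cul-4. The authors' deposited table called 16 of 18 higher with OMA-1, and 16 when adjusted over the list alone. With equal totals 11 were higher and 4 lower (median 2.07 to 0.73), and with quantile normalization 10 and 6 (0.63). That list was drawn up with knowledge of the study, so its count is not independent evidence. In the authors' deposited table, the log2 ratio was -1.003 for mei-1 and -1.08 for cul-4, and both were lower by the approximate test. The Notch receptor gene glp-1 had a log2 ratio of 3.02 in the authors' deposited table, and its FPKM rose from 103 to 842. All 11 PUF, FBF and Nanos genes were called in the authors' deposited table, and 11 when adjusted over the list alone, with puf-6 at 3.70 and nos-2 at 3.71. With equal totals 7 of them were higher and 2 lower, and with quantile normalization 8 and 3. The embryonic polarity and germ plasm list had 18 of 22 genes called in the authors' deposited table and 1 lower by the approximate test, with a median log2 ratio of 1.45; with equal totals 10 were higher and 9 lower (0.12), and with quantile normalization 10 and 10 (0.07). Of 25 genes for the meiotic chromosome axis and recombination, 23 were called in the authors' deposited table, with cosa-1 at 4.09 and him-8 at 4.04. The eggshell list had 11 of 14 genes called and the P granule list 12 of 20 in the authors' deposited table, with gld-1 at 4.37 and car-1 at 3.84. Adjusted over the list alone, these counts were 18, 23, 11 and 12. Equal totals turned the medians of the meiotic axis list (0.99 to -0.35), the eggshell list (1.098 to -0.24) and the P granule list (0.69 to -0.64) negative, and quantile normalization did so for the eggshell (-0.53) and P granule (-0.60) lists.

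All 12 genes of the mitochondrial genome were called higher with OMA-1 in the authors' deposited table, and 12 when adjusted over the list alone, with a median log2 ratio of 2.73 and ctc-2 at 3.90; with quantile normalization 10 were higher and 1 was lower. Mitochondrial ribosomal protein genes, encoded in the nucleus, were mixed, with 29 of 66 called in the authors' deposited table and a median of 0.23 that fell to -1.11 with equal totals and -0.17 with quantile normalization. By the approximate test, 73 of 76 cytosolic ribosomal protein genes were lower, while rps-29 (1.47) and the list member F54D7.6 (1.23) were called higher in the authors' deposited table. Of these, F54D7.6 turned negative with both scalings and rps-29 with quantile normalization. Proteasome genes were lower in 30 of 33, with rpn-6.2 (0.76, and -0.58 with equal totals) called higher in the authors' deposited table. Body wall muscle genes were lower in 12 of 13, and of the histone genes 25 of 38 were lower and 5 were called higher, among them his-41 at 3.12 in the authors' deposited table. The RNase P RNA rpr-1 (-7.75), the RNase MRP RNA mrpr-1 (-7.28) and the small RNA gene sup-6 (-6.82) had the lowest log2 ratios of the ranked genes in the authors' deposited table, followed by rps-8 (-4.29), rpl-38, dod-24, pud-3 and cyc-2.1 (-3.85). In all, 2910 genes were lower by the approximate test, 2040 of them at least 2-fold. Fisher's exact test, adjusted over the lists, gave 9 lists called more often than other genes, among them those of the mitochondrial genome and the PUF genes, and 4 less often, the ribosomal protein, proteasome, muscle and hypodermis lists. Among random lists matched on lysate FPKM, the mitochondrial genome median lay at percentile 99.99 and the PUF median at 99.9. Lists called more often with lower percentiles were mitochondrial ribosomal proteins (30.4), P granule (89.8), meiotic axis (92.5) and eggshell (94.6).

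The remaining lists were mixed with OMA-1 under the deposited scaling. The authors' deposited table called 8 of 23 M-phase genes, 3 of 12 meiotic spindle genes, 3 of 14 replication licensing genes, 5 of 17 ubiquitin ligase genes and 5 of 12 sheath and yolk uptake genes. By the approximate test, 10 M-phase, 7 meiotic spindle, 8 licensing, 10 ubiquitin ligase and 2 sheath genes were lower. With equal totals these 5 lists had, in that order, 3, 1, 1, 3 and 0 genes higher and 17, 10, 12, 13 and 11 lower. With quantile normalization they had 2, 1, 0, 3 and 0 higher and 20, 11, 12, 13 and 6 lower. The authors' deposited table called 3 of 12 neuron genes, 1 of 13 intestine genes, and none of 12 hypodermis, 6 pharynx or 7 sperm genes, while 3 neuron, 8 intestine, 4 hypodermis, 3 pharynx and 0 sperm genes were lower. The intestine gene was vit-3, which may share reads with its copies and turned negative with both scalings. The tagged genes and their paralog were all called in the authors' deposited table, with log2 ratios of 3.04 for oma-1, 3.42 for oma-2 and 1.80 for lin-41, which fell to -0.05 with quantile normalization. The authors' deposited table called 3 of 8 heat shock genes, with hsp-4 at 3.77, and adjusted over the list alone 4 passed; their median of 0.51 became -0.82 with equal totals and -0.19 with quantile normalization. Adjusted over the list alone, the other counts did not change. No gene of the ribosomal RNA list was in the table.

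Which mRNAs came down with LIN-41 was asked next. In the deposited values the highest log2 ratios belonged to mab-10, lin-29 and mab-3, regulators of larval development that LIN-41 also controls outside the germ line. They were followed by orc-1, a replication origin gene, spn-4, an RNA-binding protein gene of early embryos, and cdc-25.3, a cell cycle phosphatase gene. In the authors' deposited table, mab-10 (WBGene00003107, II 10528084 to 10534380) had a log2 ratio of 8.66, from 3.64 FPKM in the lysates to 1483 FPKM in the IPs. For lin-29 (WBGene00003015, II 11917642 to 11935343) the authors' deposited table gave 7.10, and for mab-3 it gave 7.17, with 0.32 FPKM in the lysates. With a pseudocount of 1 FPKM, mab-3 fell to 5.25 and lin-29 to 6.28, both below orc-1, and mab-10 stayed highest of these at 8.32. The authors' deposited table gave orc-1 (WBGene00012650, III 10643129 to 10646058) a log2 ratio of 6.602, spn-4 (WBGene00004984, V 6783187 to 6784903) 6.21 and cdc-25.3 (WBGene00000388, III 8916351 to 8917929) 6.08. The FPKM of spn-4 rose from 579 to 43194 in the authors' deposited table. The authors' deposited table listed nfyc-1, impt-1, mis-12, laat-1, sdz-21, jmjd-2, zif-1 and lsd-1 between 5.70 and 5.24. With quantile normalization orc-1 fell to 4.74 and spn-4 to 4.18, below all of these genes but zif-1 (3.80). Of 13955 genes tested, the authors' deposited table called 3795 (27.2%) higher with LIN-41, 2588 at least 2-fold and 149 at least 16-fold.

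Oocyte and embryo lists were enriched with LIN-41 as well. The authors' deposited table called 16 of 18 reported targets, and 17 passed when adjusted over the list alone, a list that is not independent evidence. With equal totals 14 targets were higher and 3 lower, and with quantile normalization 14 and 2. Not called in the authors' deposited table were cul-4 (-0.05) and fce-2 (0.41). Of the polarity and germ plasm genes, 21 of 22 were called in the authors' deposited table, with neg-1 at 5.15 and a median of 2.27. Of the meiotic spindle genes, 9 of 12 were called in the authors' deposited table, among them aspm-1 at 1.88, and their median of 0.77 became -0.18 with equal totals and -0.14 with quantile normalization. The authors' deposited table called 11 of 14 eggshell genes, with mbk-2 at 3.75 and egg-5 at 2.77, and 10 of 11 PUF, FBF and Nanos genes, with nos-1 at 5.06. Of the eggshell genes, 8 were higher and 5 lower with equal totals (median 1.41 to 0.46), and 6 and 6 with quantile normalization (0.21). The authors' deposited table called 20 of 25 meiotic axis genes, whose median of 0.82 became -0.13 with equal totals. Of the P granule genes 13 of 20 were called in the authors' deposited table, and 15 when adjusted over the list alone, and their median of 0.50 became -0.45 with equal totals and -0.42 with quantile normalization. The authors' deposited table called 11 of 23 M-phase genes (median 0.15; -0.80 under both scalings), 4 of 14 licensing genes (0.06; -0.90 under both), 6 of 17 ubiquitin ligase genes, 6 of 12 sheath genes (0.13; -0.82 and -0.20) and 8 of 12 mitochondrial genome genes (1.02; 0.07 with equal totals, and 4 higher and 4 lower with quantile normalization). All 3 tagged genes and paralog were called in the authors' deposited table, with lin-41 at 4.64, oma-2 at 3.23 and oma-1 at 1.66. Other counts adjusted over the list alone did not change.

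Transcripts of ribosomal proteins, the proteasome, muscle and intestine were low with LIN-41. All 76 cytosolic ribosomal protein genes, 23 of 33 proteasome genes, 13 of 13 body wall muscle genes, 12 of 13 intestine genes and 25 of 34 histone genes were lower by the approximate test. The authors' deposited table called 1 proteasome gene (rpn-6.2, 1.501), 4 histone genes (his-72 at 3.71), 18 of 66 mitochondrial ribosomal protein genes, 3 of 12 neuron genes and 1 of 8 heat shock genes (hsp-4, 0.65, and -0.30 and -0.46 after the scalings). None of 12 hypodermis genes was called in the authors' deposited table (median 0.11; -0.84 with equal totals), nor any of 5 pharynx and 5 sperm genes. In the authors' deposited table, the lowest log2 ratios of the ranked genes were those of rpr-1 (-8.25), mrpr-1 (-6.84), sup-6 (-6.82) and rps-8 (-3.63), followed by spp-14, pat-10, lbp-2 and rps-28 (-3.31). In all, 2066 genes were lower by the approximate test, 1261 at least 2-fold. Fisher's exact test gave 9 lists called more often, the meiotic spindle list among them, and 4 less often, the ribosomal protein, proteasome, muscle and intestine lists. Among random lists matched on lysate FPKM, the meiotic spindle median lay only at percentile 92.0 and the P granule median at 88.2. Of the 12 spindle genes, 2 were higher and 6 lower with equal totals, and 4 and 6 with quantile normalization.

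**Figure D1:**
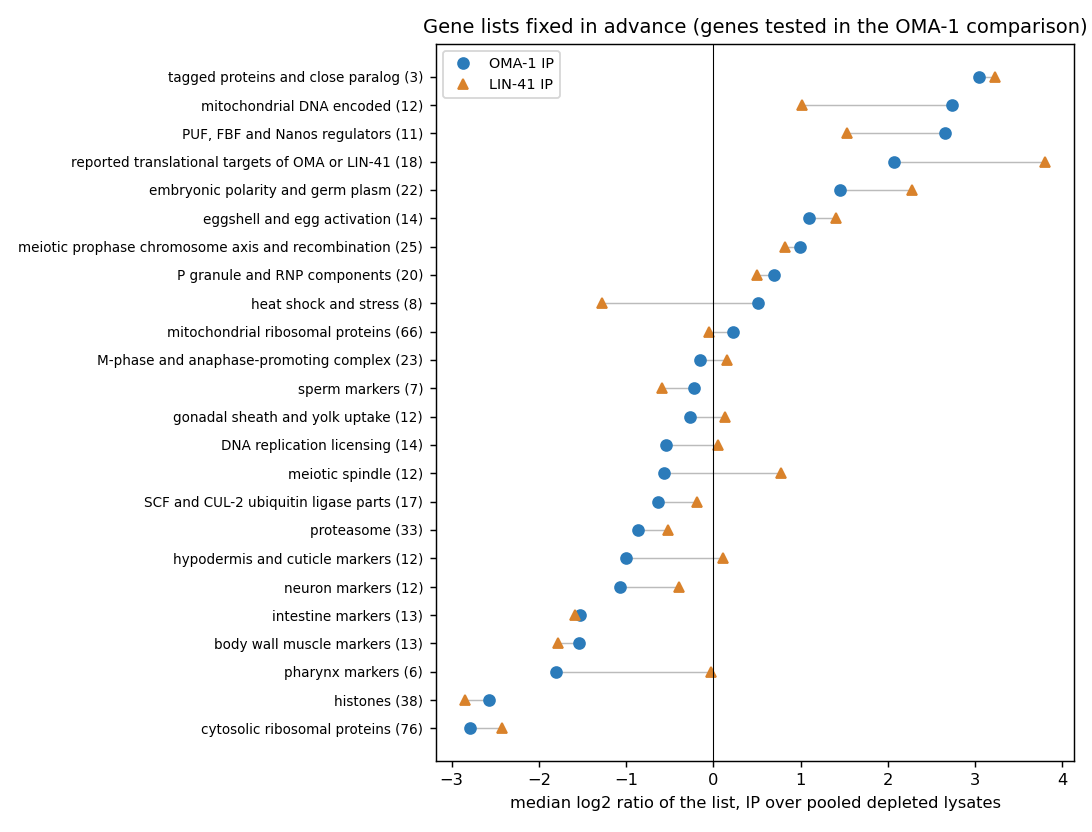
Median log2 ratio of each gene list in the OMA-1 and LIN-41 IPs, from the authors' deposited table. Medians near 0 flip sign with equal FPKM totals, which shift OMA-1 by -1.33 and LIN-41 by -0.95.

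Whether the proteins bind different mRNAs was asked with the difference of their log2 ratios, in which the lysate cancels. The LIN-41 IPs held far more lin-29, mab-10, spn-4 and orc-1 mRNA, and the OMA-1 IPs more linc-68, clec-245, fbxb-60, pqn-24 and picc-1 RNA. Reported targets split: meg-1 and trcs-1 were higher with LIN-41, while glp-1, mom-2 and rnp-1 were higher with OMA-1. The mRNA of zif-1, which encodes a ubiquitin ligase adaptor of early embryos, did not differ detectably under the deposited scaling. The OMA-1 minus LIN-41 difference was -6.24 ± 0.286 (approximate SE) for lin-29, -5.68 ± 0.187 for mab-10, -5.04 ± 0.126 for spn-4 and -4.78 ± 0.131 for orc-1. The LIN-41 adjusted p of lin-29, mab-10 and orc-1 was stored as 0 and implied no SE. The LIN-41 part of the error was therefore the OMA-1 SE for mab-10 and orc-1 and an upper limit for lin-29. It was -4.21 for trcs-1, -4.20 for arr-1, -4.03 for cfp-1, -4.03 for mis-12 and -3.90 for meg-1. It was 5.39 ± 0.905 for linc-68, 5.06 ± 0.882 for clec-245, 4.90 ± 0.848 for fbxb-60 and 4.81 ± 0.349 for pqn-24. For fipr-2 it was 4.53 ± 0.481, for ceh-51 4.40 ± 0.988, for picc-1 4.32 ± 0.173 and for pes-10 4.23 ± 0.435. The LIN-41 part of the error was borrowed from the OMA-1 comparison for linc-68, clec-245, pqn-24, fipr-2, ceh-51 and pes-10. With errors this wide, the order of these genes is uncertain. Of these, clec-245 and fbxb-60 belong to large families and had under 1 FPKM in the lysates, as did linc-68. In the LIN-41 IPs the authors' deposited table gave 0.25 FPKM for clec-245, 0.45 for linc-68 and fbxb-60, and 0.66 for ceh-51. The authors' deposited table gave picc-1 80.0 FPKM in the lysates, 4294 with OMA-1 and 214 with LIN-41. The difference for zif-1 (WBGene00006977, III 9002779 to 9004839) was -0.02, with an adjusted p of 0.972. With equal totals its log2 ratios were 3.92 with OMA-1 and 4.32 with LIN-41, and with quantile normalization 3.37 and 3.80.

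By list, 13 of 22 polarity and germ plasm genes were higher with LIN-41 and 4 with OMA-1, and 13 M-phase, 8 meiotic spindle and 8 licensing genes were higher with LIN-41 against 0, 1 and 0 with OMA-1. Of the reported targets 10 were higher with LIN-41 and 6 with OMA-1. The mitochondrial genome had 9 of 12 genes higher with OMA-1 and none with LIN-41, and the heat shock list 5 of 8 and none. The meiotic axis list had 13 genes higher with OMA-1 and 2 with LIN-41, with a median difference of 0.46 that became -0.07 with quantile normalization. Over 13955 genes, 2745 were higher with OMA-1 (2076 at least 2-fold, 282 at least 8-fold) and 1731 with LIN-41 (1011 and 72). The share higher with OMA-1, 61.3%, became 49.7% with quantile normalization and 41.7% with equal totals, so no overall direction is given. Each IP came from its own strain and culture, so protein and strain cannot be told apart.

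**Figure D2:**
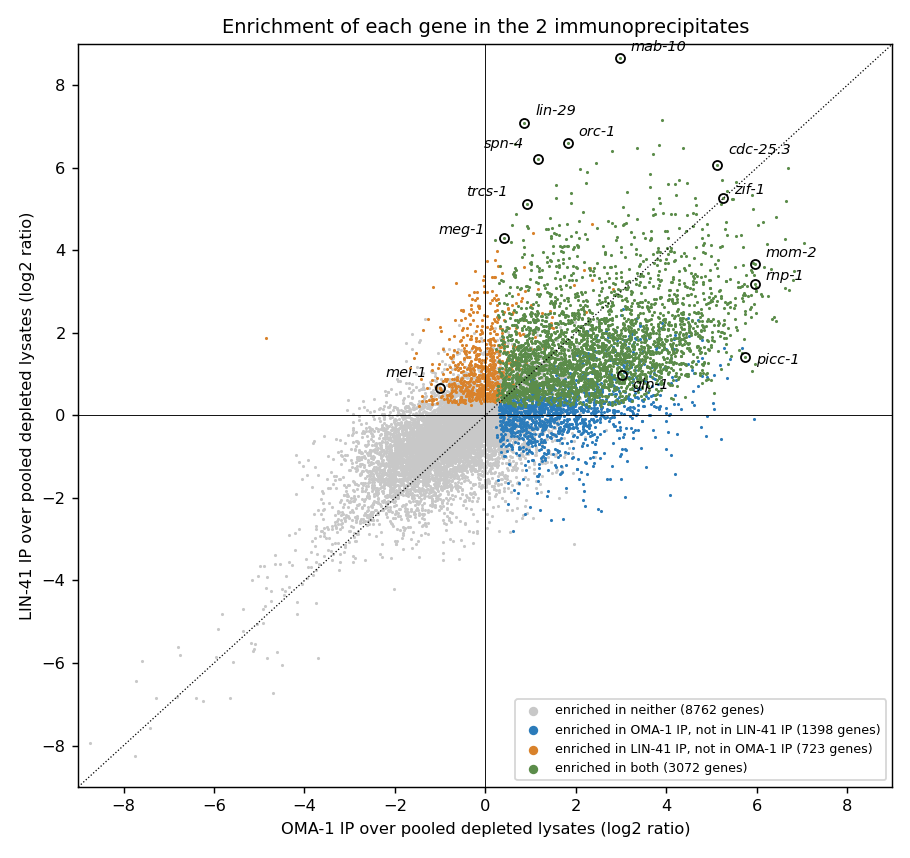
Log2 ratio of each gene in the OMA-1 and LIN-41 IPs over the pooled lysates, from the authors' deposited table.

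**Figure D3:**
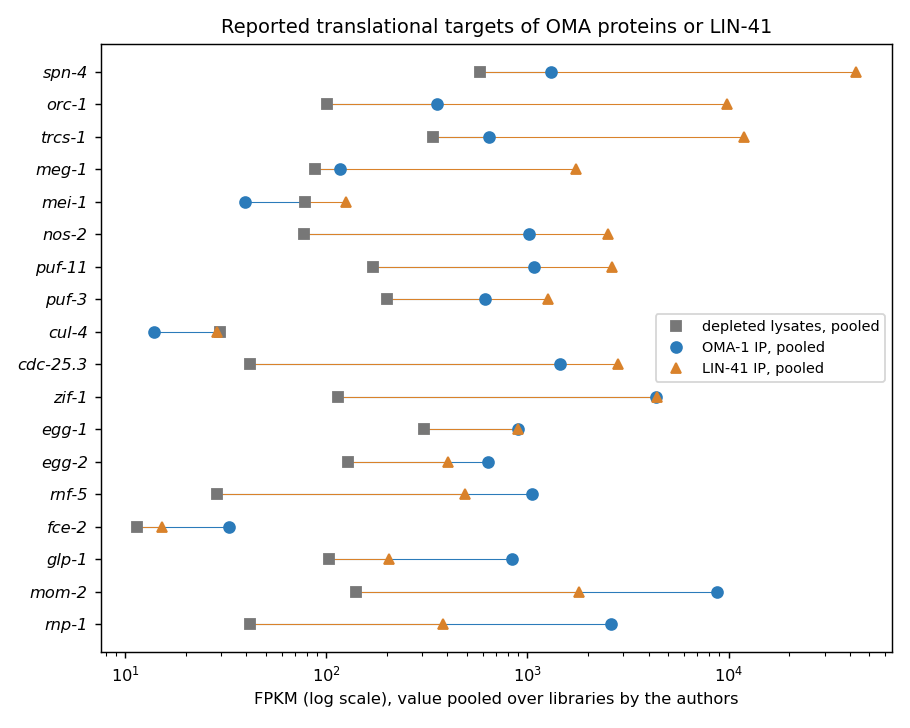
FPKM (log scale) of the reported targets in the pooled depleted lysates, the OMA-1 IPs and the LIN-41 IPs, from the authors' deposited table. For spn-4, trcs-1 and meg-1 the OMA-1 log2 ratio over the lysates, and for mei-1 the LIN-41 ratio, turns negative with both scalings. With quantile normalization so do the OMA-1 ratios of orc-1, puf-3 and egg-1 and the LIN-41 ratio of glp-1.

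Which mRNAs came down with both proteins was asked last. The genes with the highest summed ratios included impt-1, cdc-25.3, sygl-1, sdz-21, sdz-37, mab-3, mab-10, nfyc-1, lsd-1 and zif-1. In the authors' deposited table, impt-1 had log2 ratios of 5.53 and 5.64, and lsd-1 of 5.44 and 5.24, for OMA-1 and LIN-41. Both IPs enriched 3072 genes, 68.7% of the OMA-1 calls and 80.9% of the LIN-41 calls, where independent lists would share 1216. Of these, 1599 were higher with OMA-1, 520 with LIN-41, and 953 passed no difference. Called with OMA-1 alone were 1398 genes, of which 905 also passed the difference, and with LIN-41 alone 723, of which 539 did. Lower in both were 1466 genes, where 430.5 would be shared by independent lists. Across genes, which are not independent replicates, the log2 ratios correlated with r = 0.719. In simulated data without effects, the shared lysate alone gave r = 0.498 and a covariance of 0.197, against a covariance of 1.73 observed. The simulation gave the lysate and the IPs equal spread, which fixes that r in advance. No gene was called in both in 20 draws. Without effects hardly any gene can be called, so this does not measure the lysate's part in the overlap. The excess over independent lists may still hold a part from the shared lysate. Over 6768 genes with a baseMean of at least 100 the covariance was 1.97, where random spread of the shared lysate alone would give 0.0186 under the same equal spread. Any systematic difference between IPs and lysates that both IPs have, such as depletion of the lysates alone or nonspecific carry-over, also adds covariance. The gap therefore does not show that the proteins bind the same mRNAs. The depleted against undepleted lysates, the strains' lysates, and each IP against its own lysate were not analysed here.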

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

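The tests on mitochondrial transcripts, on selection by the tagged protein and on transgene-linked genes were chosen only after the results were seen, and so was the test of the difference itself, which departs from the plan. The histone variant test was written after histone genes were seen to be low and before the variants were compared.

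Each gene below had an OMA-1 minus LIN-41 log2 difference that passed the approximate test at an adjusted p below 0.05. Higher with LIN-41 among its most enriched or most different genes were lin-29 (-6.24), mab-10 (-5.68), mab-3 (-3.26), arr-1 (-4.20), cfp-1 (-4.03), laat-1 (-3.49), jmjd-2 (-1.11) and nfyc-1 (-0.48). Higher with LIN-41 among oocyte and embryo genes were spn-4 (-5.04), trcs-1 (-4.21), meg-1 (-3.90), nos-1 (-2.01), nos-2 (-1.303), mex-3 (-1.56), neg-1 (-1.28), puf-3 (-1.03), puf-11 (-1.28), mbk-2 (-2.31), egg-5 (-1.31), rme-2 (-0.52), cav-1 (-1.24) and lin-41 (-2.83). Cell cycle, spindle and ubiquitin ligase genes on that side were orc-1 (-4.78), mis-12 (-4.03), cdc-25.2 (-1.63), cdc-25.3 (-0.95), cdt-1 (-1.51), aspm-1 (-2.09), mei-1 (-1.68), zyg-11 (-3.17) and cul-4 (-1.03). Genes of other kinds were dod-24 (-2.98), pud-3 (-2.80), myo-1 (-2.48), myo-2 (-2.26), unc-22 (-0.68), snb-1 (-0.56), col-140 (-1.35), col-119 (-1.303), his-72 (-1.54), mrpl-45 (-1.41), rpl-38 (-1.36) and rps-8 (-0.66). Several of the last set were low in both IPs, so their difference is one of depletion.

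Higher with OMA-1 among its most enriched genes were dpy-10 (3.66), zip-11 (3.49), ztf-22 (3.21), mam-4 (2.97), ing-3 (2.78), rnp-1 (2.77), dad-1 (2.55), ref-1 (2.43), erg-28 (2.35), sygl-1 (2.35), mom-2 (2.28), num-1 (2.08) and sdz-37 (0.90). Furthest toward OMA-1 were linc-68 (5.39), clec-245 (5.06), fbxb-60 (4.90), pqn-24 (4.81), fipr-2 (4.53), ceh-51 (4.40), picc-1 (4.32) and pes-10 (4.23). Oocyte, germline and protein turnover genes on that side were him-8 (3.25), cosa-1 (2.74), gld-1 (2.53), puf-6 (2.17), glp-1 (2.04), car-1 (1.98), zer-1 (1.67), oma-1 (1.39), rnf-5 (1.103), fce-2 (1.11), syp-3 (1.02), tac-1 (1.02), cpg-1 (1.02), cey-3 (0.67) and egg-2 (0.66). Mitochondrial, ribosomal and stress genes were ctc-2 (2.66), nduo-5 (2.07), atp-6 (2.06), mrpl-36 (2.32), mrpl-30 (2.15), mrps-10 (1.43), rps-29 (1.93), F54D7.6 (1.80), rps-3 (1.54), hsp-16.41 (3.57) and hsp-4 (3.13). The rest were vit-3 (2.61), his-41 (1.90), his-71 (1.69), unc-64 (1.63), unc-54 (1.24), pat-10 (1.04) and rpr-1 (0.50). Some genes on this side were low in both IPs, so their difference is one of depletion. Among them, the OMA-1 and LIN-41 log2 ratios in the authors' deposited table were -7.75 and -8.25 for rpr-1, -2.32 and -3.36 for pat-10, and -0.35 and -1.88 for rps-3. Copies of vit-3, the hsp-16 genes, puf-3, puf-11, puf-6, egg-2 and the histone genes may share reads, and scaling columns to equal totals lowers every difference by 0.38. For vit-3, that setting gave an OMA-1 log2 ratio of -0.15.

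All 12 genes of the mitochondrial genome, such as ctc-2 and nduo-5, were called higher with OMA-1 under the deposited scaling, and with quantile normalization 10 were higher and 1 lower. Scaling the FPKM columns to equal totals left their median log2 ratio at 1.38, against scaling as the whole cause. Carry-over alike in every IP was argued against by the median difference of 1.73 between the IPs. A spread within the libraries stays open. Although 9 of the 12 passed the difference, their implied SE lay at the median percentile 92.5 of genes of like baseMean. In the OMA-1 IP of the earlier study, set over the same lysates, the 12 genes had a median log2 ratio of 2.64. The high median thus recurred outside these OMA-1 libraries. Spread among the LIN-41 libraries or the lysates was not excluded. Strain or culture cannot be told apart from the protein, because the lysates were pooled over strains, and no biological explanation was tested.

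Histone, snRNA and snoRNA genes were low in both IPs, with medians of -5.02 for 11 snRNA genes in the OMA-1 IPs and -1.33 for 142 snoRNA genes. A preference of the IP libraries for polyadenylated RNA is a candidate explanation: the variants his-24, his-35, his-71 and his-72, whose mRNA is polyadenylated, lay above the other 34 histone genes by 3.14 with LIN-41 and 3.71 with OMA-1. The exception was his-35, at -2.42 and -1.84 in the authors' deposited table. Selection by the tagged protein stays open: the median difference between the IPs was 0.0163 over 187 genes that went both ways, and selection alike in both IPs would also give a value near 0. Exclusion of nuclear RNA from cytoplasmic complexes was not tested, nor was an effect of depleting only the lysates.

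The genes unc-119, lin-41 and oma-1, which the transgene and the tag touch, had wide implied SEs, at percentiles 99.5, 97.0 and 87.6 of genes of like baseMean. The bound set for strains that differ at these loci, pooled in the lysate, was all 3 in the top 5%. That bound was not met, as oma-1 lay at 87.6. It cannot decide the question, because an implied SE holds the spread of the IPs as well as that of the lysates. For unc-119 the implied SE was 0.811, and its log2 ratio of 1.72 with OMA-1 in the authors' deposited table was not called. No biological explanation was tested.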

How the results depend on the processing

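The settings without multimapping genes, with the median error of neighbours and with the larger single error were chosen after seeing the data. Named genes kept their direction and side of the threshold in 181 of their log2 ratios with equal totals and 208 with quantile normalization. With equal totals, 22 that had passed changed sign, 21 lost their call, 11 gained one and 7 others changed sign. With quantile normalization these counts were 24, 7, 4 and 5. With pseudocounts of 1 and 0.1 FPKM, 214 and 246 stayed within their error and 34 and 2 did not. With equal totals, which lower every ratio by construction, 2211 genes were higher with OMA-1 and 1789 with LIN-41, all of them among the deposited calls, 8179 and 6617 were lower, 2884 were higher in the LIN-41 IP, and 1170 were called in both. With it, 4 lists were called more often and 2 less often for OMA-1, and 5 and 1 for LIN-41. OMA-1 log2 ratios that reversed were lin-29 -0.47, spn-4 -0.16, trcs-1 -0.41, arr-1 -0.67, cfp-1 -1.12, meg-1 -0.93, cdt-1 -0.95, rpn-6.2 -0.58, F54D7.6 -0.10, mrpl-45 -1.03, rab-11.1 -0.28, rme-2 -0.45 and vit-3 -0.15. LIN-41 log2 ratios that reversed were mei-1 -0.28, tac-1 -0.084, him-8 -0.16, mrpl-36 -0.023, rab-11.1 -0.14, unc-64 -0.30, snb-1 -0.18, hsp-4 -0.30 and his-24 -0.20. With quantile normalization 3135 genes were lower with LIN-41, and 3 lists were called more often and 2 less often for OMA-1, and 5 and 2 for LIN-41. Its reversed OMA-1 log2 ratios were orc-1 -0.038, spn-4 -0.43, trcs-1 -0.78, cfp-1 -0.86, lin-41 -0.047, meg-1 -1.18, puf-3 -0.24, egg-1 -0.14, mbk-2 -0.42, mesp-1 -0.29, mcm-7 -0.53, cdt-1 -0.00492, mex-3 -0.47, rps-29 -0.20, F54D7.6 -0.51, mrpl-45 -0.89, rab-11.1 -0.80, rme-2 -0.83 and vit-3 -0.72. Its reversed LIN-41 log2 ratios were glp-1 -0.10, mei-1 -0.30, rab-11.1 -0.28, snb-1 -0.12 and hsp-4 -0.46. Why these genes reversed under quantile normalization was not examined, and the cause was not tested. With a 2-fold minimum, which removes genes by construction, 1261 genes were lower with LIN-41, 1011 were higher in the LIN-41 IP, 1964 were called in both, and 2 lists for OMA-1 and 1 for LIN-41 were called less often. With the filter at 10 FPKM, which tests fewer genes, 5 lists for OMA-1 and 4 for LIN-41 were called more often. The settings chosen later kept every count within 1.5 times.

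No paired analysis was possible because no values per library were held. Planned and not run for that reason were other tools, size factors, leaving out each replicate, replicate blocks, own, undepleted or combined lysates as the reference, fits on fewer libraries, no filter, and an estimated correlation in set tests. Depth per library is unknown. Genes of low baseMean carry the widest errors. The median implied SE for OMA-1 was 1.18 at a baseMean of 1 to 10, 0.518 at 10 to 100 and 0.101 above 10000. Small differences in rare transcripts were therefore not detectable.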

Other observations

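The test of oogenic expression was chosen only after the results were seen, and the gonad and gene family counts were not planned. The tests of 3′ UTR length and of the X chromosome were written before their results were seen.

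Genes expressed more in oogenic gonads were called more often with both proteins than other genes. By the gonad comparison of another study in the authors' deposited table, 2432 of 13501 genes were oogenic, 2277 spermatogenic and 8792 neither. Oogenic genes were at least 2-fold higher in oogenic gonads at an adjusted p below 0.05 in that comparison. OMA-1 calls covered 53.0% of oogenic, 15.3% of spermatogenic and 31.5% of other genes, and LIN-41 calls 53.5%, 7.91% and 26.2%. The classes were not matched on lysate FPKM or baseMean. Genes of low baseMean have the widest errors and are harder to call, and the animals were feminised. Different expression of the classes in these animals may thus account for part of the gap, which was not tested. Oogenic genes may be called more often because both proteins act in oocytes: the odds ratio against all other genes was 2.87 for OMA-1 and 3.97 for LIN-41, and 2.76 and 4.05 with equal totals, where the shares of oogenic genes called fell to 29.7% and 29.98%.

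Among 158 gene name prefixes with at least 8 tested members, OMA-1 called 13 of 13 ced genes, named for cell death defects, and LIN-41 10, and of 8 sqv genes, which act in glycosaminoglycan synthesis, OMA-1 called 8 and LIN-41 5. Both proteins called 7 of 8 rsp genes, which encode splicing factors, and 8 of 10 puf genes. Of 30 set genes LIN-41 called 20 and OMA-1 16, and of 19 rab genes 14 and 11. Among the 13955 genes tested in both comparisons, on which these counts rest, 4470 were called with OMA-1 and 3795 with LIN-41. At those shares, 32.0 of 100 genes would be called with OMA-1 and 27.2 with LIN-41. By Fisher's exact test, adjusted over the prefixes of each IP, set (adjusted p 0.106) and rab (0.127) did not pass with OMA-1. Nor did sqv with LIN-41 (0.136). The other excesses named above passed. Of 101 col genes, which encode cuticle collagens, 10 were called with OMA-1 and 1 with LIN-41, and none of 29 flp neuropeptide genes was called with either. Of 100 fbxb and 90 clec genes, whose copies may share reads, OMA-1 called 9 and 6 and LIN-41 called 2 and 4. In contrast to its family, fbxb-60 had an OMA-1 log2 ratio of 5.06 in the authors' deposited table. These families were picked after their values were seen, and the oogenic odds ratio of 2.87 may account for part of them.

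Transcripts enriched with LIN-41 had longer annotated 3′ UTRs, with a median of 211 nt against 136 nt for genes not called, among the 94.3% of tested protein-coding genes with an annotated 3′ UTR. Within 4 bins of lysate FPKM the ratio ran from 1.305 to 1.57, which is consistent with binding through 3′ UTRs and also with better annotation of germline genes. For OMA-1 the ratio ran from 1.09 to 1.28, so the 1.2-fold bound was not met in every bin. Of X-linked genes 16.8% were called with both proteins, against 22.9% of autosomal genes, a ratio of 0.734 that lay between the bounds set for rare and for equal. The low share was not particular to X: chromosome V had 16.7%, and the other autosomes 22.5% to 27.9%.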
